A study of Homo sapiens with 23 samples.

How the data were processed

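The series held 23 chromatin immunoprecipitation sequencing libraries from 2 human pancreatic ductal adenocarcinoma lines, 19 from CFPAC1 and 4 from PANC1. The targets were FOXA2 (14 libraries), FOXA1 (3), Flag-tagged HOXB8 (2), H3K27ac (2), JUNB (1) and FOS (1). Per the labels' protocols, chromatin was fixed with formaldehyde, with an added protein cross-linker before it for FOS. The labels describe an early protocol with column clean-up and a late one with bead clean-up, and these were treated as batches.

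Per the submitters' processing notes, the tools were Trimmomatic 0.38, Bowtie2 2.2.6, SAMtools and MACS2 2.1.0.20150731, with the build GRCh38 (hg38). The deposited files are 1 peak list per library, with each peak's position and summit. The fold enrichment of each peak over local background, a ratio, is the authors' value as deposited. The −log10 p and −log10 q of each peak are likewise as the authors deposited them. The deposited score is 10 times −log10 q in 14 lists and 10 times −log10 p in the other 9. Those 9 lists, which are the FOXA1 libraries and the FOXA2 libraries of the FOXA1KO, FOXA2KO and FOXA2WT clones, reach down to a −log10 q of 0.658, whereas the lowest value in the other 14 is 1.30. The limit used in calling thus differed between lists. The control library used in calling is not given in the sources used here. Folds and p-values of peaks were used only to describe, rank or filter peaks within a list, since values from separately called lists are not on a common scale.

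Read depth per sample is unknown from peak lists. List length ranged from 16619 to 130094 peaks and stands in for no depth. Peaks outside chromosomes 1 to 22 and X, at most 0.0839% of any list, were left out. No pair of lists held identical peaks (0 pairs).

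Lists were compared by overlap of at least 1 bp. For the comparison of the lines, peaks of 9 FOXA2 libraries were merged into sites where they overlapped. These were 6 CFPAC1 libraries of cells with neither factor edited nor HOXB8 added, and 3 such PANC1 libraries. A CFPAC1-only site was called in at least 4 of the 6 and none of the 3, a PANC1-only site in at least 2 of the 3 and none of the 6, and a shared site in at least 4 and at least 2. The share of each library's 5000 strongest peaks (by −log10 p) whose summit lay in a CFPAC1 JUNB, FOS or H3K27ac peak, the last called in both libraries, was compared between lines with a two-sided exact permutation test over all 84 splits. Benjamini-Hochberg adjustment ran over the 4 shares. The same summits moved by 50 kb to either side gave the background.

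Gene positions came from an NCBI RefSeq table of the same build with 19974 protein-coding genes. It gives no strand, so a planned distance to the transcription start was replaced by the distance to the nearer end of the gene, of 1 kb for "gene end" and 50 kb for gene lists. The 8 gene lists were epithelial and classical PDAC genes, mesenchymal genes, AP-1 members, HOX clusters, basal-like or squamous genes, liver genes, and haematopoietic and neural genes as markers of other cell types. Each was tested with a two-sided Fisher's exact test against the other genes within 50 kb of a site of any of the 3 classes, adjusted over 16 tests. Neighbouring genes share sites, so each list was also shifted along the order of genes. A planned count of sequence motifs was not run, because no genome sequence was used here.

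For edited cells, the share of sites called in both control libraries and also in both edited libraries was taken, and the converse. Sites gained with HOXB8 were called in the HOXB8 library and in none of the 6 control CFPAC1 FOXA2 libraries. Lost sites were called in the empty-vector library and at least 3 of the other 5 controls, and not with HOXB8. Kept sites were called in the HOXB8 library, the empty-vector library and at least 3 of the other 5 controls. For sites called by a single CFPAC1 library alone, and for tests of gained sites beside them, peaks were merged without the PANC1 lists, which gave 2001 gained sites in place of 1988. Intervals of shares are 95% Wilson intervals. They cover counting error only, and neighbouring sites are not independent. The replicates of PANC1 FOXA2 and those of CFPAC1 FOXA2 came from different cells, the original line and a clone. For other replicates, nothing in the labels says that they came from separate cultures. The p-values of permutation tests over splits of libraries thus measure the spread between these samples. That spread mixes kinds of cells and batches and may in part be technical. The p-values of the gene lists, from Fisher's exact test or shifted lists, come from counts of genes near a fixed set of classed sites. These gene-list p-values hold no spread between libraries. Several control libraries came from clones or vector-carrying cells of a line rather than the original line.

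Named sites were chosen by rule. For the lines these were the 10 per class with the highest mean percentile rank of −log10 p among sites called in every library of the line, 1 per nearest gene. In the other comparisons they were the 5 highest per direction, and for gene lists up to 6 members, some of which are not reported here. FOXA1, FOXA2 and HOXB8 were always reported. The groups, these rules, the tests, the gene lists and most alternatives were fixed before the data were examined. Alternatives covered the peak threshold, list length, overlap, batch, antibody lot, gene distance and each library left out.

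The code was tested on simulated data. With sites planted in 9 lists, 1996 of 2000 CFPAC1-only, 993 of 1000 PANC1-only and 991 of 1000 shared sites were recovered, with 80 false PANC1-only calls from peaks that coincided by chance. All 20 simulated lists of enriched genes were found. The simulated site lists were of like length with a high call rate in each, unlike the real lists, and the enriched genes were placed at random. These checks thus test the code and do not give error rates for the real lists or for clustered genes. Merging the 9 real lists gave 108284 sites both with this code and with bedtools 2.31.1. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.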

Results

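The data are peak lists of transcription factor binding and of H3K27ac, a mark of active enhancers and promoters, in CFPAC1 and PANC1 cells. Both are lines of pancreatic ductal adenocarcinoma (PDAC), and the study's title concerns the part FOXA2 plays in cells of different differentiation grade. FOXA2 and FOXA1 are related forkhead factors that bind enhancers of endodermal and epithelial genes. The 14 FOXA2 libraries fell into original or control cells of each line, CFPAC1 clones edited in FOXA1 or FOXA2, and CFPAC1 cells carrying HOXB8. FOXA2 lists of control cells held 27321 to 78605 peaks in CFPAC1 (mean 47435 ± 20167, SD, n = 6) and 17738 to 31336 in PANC1 (24213 ± 6822, SD, n = 3). This difference in length did not pass a two-sided exact permutation test (p = 0.0833). The median fold of the authors' peaks in these 23 lists lay between 4.74 and 7.26.

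CFPAC1 and PANC1 were compared to see where FOXA2 is bound in each line. Each line held FOXA2 sites that were not called in the other. Of 34659 sites called in at least 4 of the 6 CFPAC1 libraries, 21491 (62.0%) were called in no PANC1 library and 10021 (28.9%) were shared. Of 21237 sites called in at least 2 of the 3 PANC1 libraries, 7211 (34.0%) were called in no CFPAC1 library, 66.0% in at least 1, and 47.2% were shared. The larger number of CFPAC1-only sites depended on the number of peaks per list: with the 10000 strongest peaks per library there were 5511 CFPAC1-only, 5355 PANC1-only and 2938 shared sites. The strongest CFPAC1-only sites included one 2.52 kb outside CEACAM6, an epithelial adhesion molecule (chromosome 19, 41774212 to 41775821, hg38), and one in ST6GALNAC1, a sialyltransferase (chromosome 17, 76641310 to 76642169). The strongest PANC1-only site lay in NFATC2, a transcription factor (chromosome 20, 51460741 to 51461850).

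The other strongest CFPAC1-only sites lay in CLIC5 (chromosome 6, 46061692 to 46063024), LRRC8D (chromosome 1, 89826470 to 89827087), STXBP6 (chromosome 14, 24982216 to 24983577) and ALCAM (chromosome 3, 105386828 to 105388328). Outside genes, they lay nearest to AHSG, a plasma protein gene of the liver (6.62 kb, chromosome 3, 186605579 to 186606724), LDB2 (59.0 kb, chromosome 4, 16441897 to 16443044), RGS1 (62.9 kb, chromosome 1, 192512024 to 192513417) and LOC124903401 (491 kb, chromosome 14, 84465152 to 84466492). All 10 summits lay in JUNB and FOS peaks of CFPAC1, and only that of ALCAM in an H3K27ac peak called in both libraries. A summit outside such a peak need not mean a site without H3K27ac. Of the 5000 strongest peaks of CFPAC1 FOXA2 replicate 1, 29.8% had their summit in such a peak. By any overlap of the whole peak with H3K27ac replicate 1 alone, the share was 76.0%. Such overlap was not examined for these named sites. In PANC1, further sites lay in BFSP2 (chromosome 3, 133452403 to 133454145), TMEM106B (chromosome 7, 12220104 to 12221370), MBNL2 (chromosome 13, 97310784 to 97312211), ATXN1 (chromosome 6, 16754330 to 16756126) and STXBP5 (chromosome 6, 147388891 to 147390369). The rest lay in FBXO10 (chromosome 9, 37546626 to 37547653), SBF2 (chromosome 11, 10095430 to 10096940) and IQCJ-SCHIP1 (chromosome 3, 159627214 to 159628552), and 288 kb from DAB2 (chromosome 5, 39712282 to 39714248). None of these 10 summits lay in a CFPAC1 JUNB, FOS or H3K27ac peak. The number of PANC1-only sites fell to 3626 without the PANC1 empty-vector library and to 4491 without PANC1 FOXA2 replicate 1. It was 4165 among early-protocol libraries and 15074 among late ones, of which only 1 is from PANC1.

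At the FOXA2 and HOXB8 genes, FOXA2 libraries of PANC1 held more peaks than those of CFPAC1. Within 50 kb of FOXA2 (chromosome 20, 22580998 to 22585490), the 3 PANC1 libraries held 12, 11 and 9 peaks, with highest folds of 54.8, 76.7 and 81.4, and the 6 CFPAC1 libraries held 3 to 7 peaks, with highest folds of 8.58 to 22.04. Near HOXB8 (chromosome 17, 48612346 to 48615292), the PANC1 libraries held 19, 14 and 21 peaks and the CFPAC1 libraries 1 to 8. Near FOXA1 (chromosome 14, 37589552 to 37595249), there were 2, 3 and 4 peaks in PANC1 and 4 to 11 in CFPAC1, and the highest folds overlapped, with 12.7 to 62.6 in PANC1 and 19.6 to 45.9 in CFPAC1. These counts were not tested, and the folds are on each list's own scale.

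FOXA2 peaks of CFPAC1 coincided with AP-1 peaks of CFPAC1 far more often than those of PANC1 did. JUNB and FOS are subunits of AP-1, a factor of growth and stress responses, and both were mapped in CFPAC1 only. The shares thus set overlap within a line against overlap across lines, which favours CFPAC1 in advance. They do not show whether FOXA2 coincides less with AP-1 in PANC1. Of the 5000 strongest FOXA2 peaks, 77.8% ± 3.22 (SD, n = 6) in CFPAC1 and 40.1% ± 1.63 (SD, n = 3) in PANC1 had their summit in a CFPAC1 JUNB peak. For FOS peaks the shares were 77.8% ± 3.36 and 43.6% ± 1.65. Both differences had an exact permutation p of 0.0119, the smallest that 84 splits allow, and an adjusted p of 0.0238, with all 6 CFPAC1 libraries above all 3 of PANC1. Summits moved by 50 kb lay in JUNB peaks in 1.78% to 2.08% of cases and in FOS peaks in 2.80% to 3.11%.

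The H3K27ac share by summit, also from CFPAC1 peaks alone, differed less, at 27.2% ± 1.45 in CFPAC1 (n = 6) and 23.5% ± 2.26 in PANC1 (n = 3), with an exact permutation p of 0.0238 (adjusted 0.0238) and a background of 6.26% to 6.97%. By any overlap of the whole peak, and with H3K27ac replicate 1 alone in place of peaks called in both libraries, the gap was wider. In early-protocol CFPAC1 libraries, 76.0%, 70.3% and 76.7% of the 5000 strongest peaks overlapped a peak of H3K27ac replicate 1. In early-protocol PANC1 libraries, 53.2% and 52.1% did. Peaks within 1 kb of a gene end made up 3.15% ± 0.436 in CFPAC1 and 5.31% ± 1.54 in PANC1 (exact permutation p = 0.0238, adjusted 0.0238), with a background of 2.29% to 3.14%. Within the early protocol (3 against 2 libraries), the CFPAC1 and PANC1 means were 75.5% and 40.3% for JUNB, 75.4% and 44.1% for FOS, 27.2% and 24.6% for H3K27ac and 3.31% and 6.18% for gene ends. That design cannot go below an exact p of 0.1. In the late protocol (3 against 1) they were 80.03% and 39.7%, 80.1% and 42.8%, 27.1% and 21.3%, and 2.99% and 3.58%. The H3K27ac difference of 3.68 percentage points shrank to 0.433 among the 2000 strongest peaks and lost significance there (exact permutation p = 0.631). Without PANC1 FOXA2 replicate 1, where 28 splits remain, the differences were 38.55 points for JUNB and 35.1 for FOS, both at the smallest exact permutation p of 0.0357 (adjusted 0.0714), 3.61 for H3K27ac and −1.56 for gene ends (adjusted 0.0714). H3K27ac also missed the threshold without the PANC1 empty-vector library (2.58, exact permutation test, adjusted p = 0.107) and gene ends without PANC1 FOXA2 replicate 2 (−1.90, adjusted p = 0.0714).

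**Figure D1:**
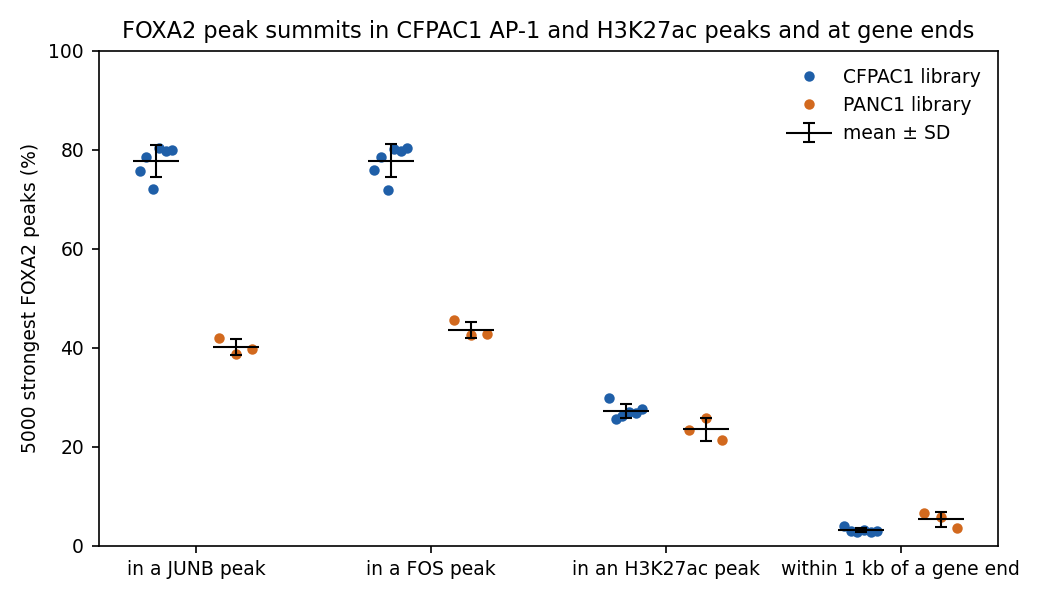
Share of the 5000 strongest FOXA2 peaks of each library (vertical axis, percent) whose summit lay in a CFPAC1 JUNB, FOS or H3K27ac peak or within 1 kb of a gene end, with 1 point per library (6 CFPAC1, 3 PANC1) and bars for mean ± SD. The JUNB shares were 72.1% to 80.3% in CFPAC1 and 38.7% to 41.9% in PANC1.

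By class, 48.7% (48.0 to 49.4) of CFPAC1-only sites had their summit in a JUNB peak, as did 50.2% (49.2 to 51.2) of shared and 1.12% (0.905 to 1.39) of PANC1-only sites. For FOS the shares were 51.3%, 54.1% and 2.52%, and for H3K27ac 25.7%, 34.0% and 5.85%. Shared sites lay within 1 kb of a gene end in 9.93% of cases, against 3.89% of CFPAC1-only and 4.26% of PANC1-only sites. Inside protein-coding genes lay 47.2% of CFPAC1-only, 57.7% of PANC1-only and 55.4% of shared sites. The classes themselves bear on the AP-1 shares, since PANC1-only sites exclude all FOXA2 peaks of the 6 CFPAC1 libraries, and those of the CFPAC1 WT library alone met 64.9% of JUNB and 51.3% of FOS peaks. The AP-1 and H3K27ac lists describe CFPAC1 alone, and PANC1 AP-1 binding was not analysed here.

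HOX clusters, whose genes encode factors of body axis patterning, stood apart among the gene lists. Of 38 HOX genes near any classed site, 30 (78.9%) lay within 50 kb of a PANC1-only site, against 36.1% of other genes (Fisher's exact test, adjusted p = 1.00e-06). Only 4 (10.5%) lay near a CFPAC1-only site, against 71.2% of other genes (Fisher's exact test, adjusted p = 1.53e-13). HOXB3 had 16 PANC1-only sites within 50 kb, HOXB4, HOXB5 and HOXB6 12 each, and HOXB7 and HOXB8 10 each, with overlapping sets of sites and no CFPAC1-only site. HOXB1 had 2 CFPAC1-only and 11 PANC1-only sites. With the list shifted along the order of genes, a test added after seeing the data, the adjusted p was 0.0209 for PANC1-only and 0.00220 for CFPAC1-only sites. The shifts keep the order of genes but not the distances between them. The deficit of CFPAC1-only sites was lost with 10000 peaks per library, where 41.9% of HOX genes had such a site (Fisher's exact test, adjusted p = 1.00).

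Within 50 kb of the clusters, HOXB (chromosome 17, 48528526 to 48626358) held 17 PANC1-only, 2 CFPAC1-only and 5 shared sites. HOXC (chromosome 12, 53938831 to 54056030) held 13 PANC1-only sites and 0 of either other class. The HOXA cluster held 3, 2 and 8, and HOXD (chromosome 2, 176087487 to 176190907) 0, 0 and 1. HOXB13 was not counted in its cluster here.

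**Figure D2:**
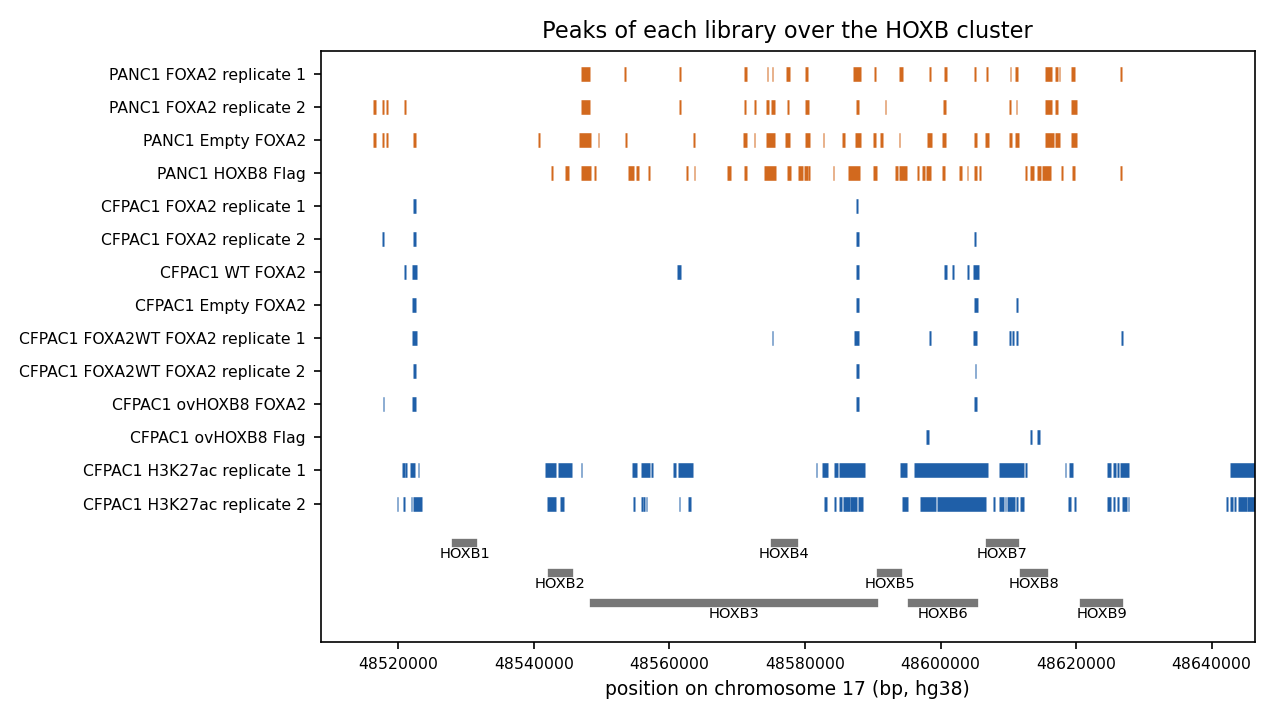
Peaks of each library (1 line per library, PANC1 in orange and CFPAC1 in blue) along the HOXB cluster and 20 kb to either side on chromosome 17 (horizontal axis, bp, hg38), with genes in grey. The 3 PANC1 FOXA2 libraries had 22, 20 and 29 peaks here and the 6 CFPAC1 control FOXA2 libraries 2 to 9, while H3K27ac had 27 and 39 peaks in the CFPAC1 libraries.

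All 15 basal-like or squamous genes near a classed site had a CFPAC1-only site within 50 kb, against 71.0% of other genes (Fisher's exact test, adjusted p = 0.0459). DSG3, a desmosomal cadherin, had 9, ITGA6 10, LAMA3 5, and SERPINB3 and SERPINB4 the same 2. The call was lost in 12 of 16 alternatives, and its adjusted p was 0.131 with the list shifted along the gene order. Near PANC1-only sites lay 5 of the 15 (33.3%, Fisher's exact test, adjusted p = 1.00), namely S100A2 with 3 sites, and KRT5, KRT6A, KRT14 and KRT17 with 1 each.

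Epithelial and classical PDAC genes did not pass the test, with 33 of 40 near CFPAC1-only sites (82.5%, Fisher's exact test, adjusted p = 0.271) and 15 of 40 near PANC1-only sites (37.5%, adjusted p = 1.00). EHF, an epithelial transcription factor, had 7 CFPAC1-only sites and no PANC1-only site, and CEACAM5, CEACAM6 and KRT20 had 3 each. AGR2 had 2 CFPAC1-only and 4 PANC1-only sites, EPCAM 3 and 2, and GATA4 had 2 PANC1-only sites and no CFPAC1-only site. TFF1 and TFF2 had 1 site of each class and TFF3 1 and 2. Mesenchymal genes were near CFPAC1-only sites in 21 of 26 cases (Fisher's exact test, adjusted p = 0.562) and near PANC1-only sites in 12 of 26 (adjusted p = 0.505). VIM, an intermediate filament gene of mesenchymal cells, had 6 PANC1-only sites and S100A4 3, with no CFPAC1-only site at either, while TGFBI had 6 and CDH2 5 CFPAC1-only sites and no PANC1-only site. TGFB2 had 4 and 3, SPARC 1 and 2, CAV1 3 and 1, and THBS1 had 3 CFPAC1-only sites and no PANC1-only site.

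AP-1 members lay near CFPAC1-only sites in 9 of 12 cases (75.0%, Fisher's exact test, adjusted p = 1.00) and near PANC1-only sites in 1 of 12 (8.33%, adjusted p = 0.267), namely BATF. JUN and MAFF had 4 CFPAC1-only sites each, FOSL2 3, and FOS and MAF 1. For liver genes the counts were 7 of 10 (Fisher's exact test, adjusted p = 1.00) and 1 of 10 (adjusted p = 0.271), with 6 CFPAC1-only sites near FGA and FGB, 4 near SERPINA1 and 3 near APOA1. Markers of haematopoietic cells gave 5 of 10 (Fisher's exact test, adjusted p = 0.332) and 1 of 10 (adjusted p = 0.271), the latter PTPRC. Neural markers gave 6 of 11 (Fisher's exact test, adjusted p = 0.505) and 4 of 11 (adjusted p = 1.00), with 5 CFPAC1-only sites near SNAP25.

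Cells edited in FOXA2 were examined first with the FOXA2 antibody itself, as a check of the labels. The libraries labelled FOXA2KO kept FOXA2 antibody peaks at nearly all control sites. Of 26129 sites called in both control libraries, 25525 (97.7%, 97.5 to 97.9) were called in both libraries labelled FOXA2KO, and 49670 sites in all were called in both of these. The lists labelled FOXA2KO held 59503 and 59600 peaks, and the longer control list, FOXA2WT replicate 1, held 61484. The check thus went against the label, and no direction is drawn from it. Sites called in both controls and neither edited library numbered 221, the strongest in PARD3B (chromosome 2, 205273482 to 205274152), SLC8A1 (chromosome 2, 40471759 to 40472364) and CACNA1D (chromosome 3, 53518596 to 53519242) and near UTP18 (chromosome 17, 51397516 to 51398139) and MDGA2 (chromosome 14, 48096801 to 48097476). The converse class held 6274, led by sites in ALDH1A2, which makes retinoic acid (chromosome 15, 58038028 to 58040543), SEMA6D (chromosome 15, 47574872 to 47575482) and NLGN1 (chromosome 3, 174072632 to 174073217), and sites nearest to CDH8 and PLPP3.

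These shares rest on the shorter control list, that of FOXA2WT replicate 2 with 27321 peaks. Without it 71.8% of control sites were called in both libraries labelled FOXA2KO, and 87.2% of edited sites in the control library instead of 51.4%. A design of 2 against 2 libraries cannot give an exact p below 0.33, so no test was made.

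In the clone labelled FOXA1KO, the FOXA2 antibody gave peaks at most control sites. Since the same antibody also gave peaks in cells labelled FOXA2KO, these peaks do not show that FOXA2 itself stays bound. Of 26207 control sites, 23620 (90.1%, 89.8 to 90.5) were called in both edited libraries, and 67.6% of 34957 edited sites were called in both controls. The 1129 sites seen in the controls alone were led by those in DPP10 (chromosome 2, 114754736 to 114755526) and PARD3B (chromosome 2, 205273482 to 205274152) and near POFUT3, ASAP1 and BUB3. The 2287 sites seen in the edited clone alone were led by those in PPP2R2B (chromosome 5, 146695510 to 146696037) and ZNF140 (chromosome 12, 133105647 to 133106702) and nearest to SPANXN2, FLRT2 and CCDC179. Without FOXA2WT replicate 2 the shares were 53.6% and 93.3%.

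The FOXA1 antibody, with 1 library per clone, also gave peaks in the clone labelled FOXA1KO. That list held 31610 peaks against 52239 in the control clone, and 55.3% (54.8 to 55.7) of control peaks were found in it, while 93.2% of its peaks were found in the control. In the clone labelled FOXA2KO, 79.6% (79.2 to 79.9) of control peaks were found, and 79.8% of its 52236 peaks were found in the control. Control peaks missing from the FOXA1KO list (23364) were led by those nearest to NRXN3 and in DPP10 (chromosome 2, 114754762 to 114755548), with others near POFUT3, RMP64 and CDH6. Its 2138 peaks absent from the control were led by those near SPANXN2, EML1, FLRT2, ETAA1 and ADGRL2. For FOXA2KO, 10663 control peaks were missing, led by DPP10, PARD3B, SLC8A1, EDIL3 and MDGA2, and 10529 peaks were absent from the control, led by ALDH1A2, SEMA6D, DUSP22, HEMK2 and CDH8. The 5000 strongest control FOXA1 peaks were found in the FOXA1KO list in 99.9% of cases. With 1 library per arm there was no test and no replicate check.

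HOXB8, a homeobox factor, was added to both lines with a Flag tag to see where it binds relative to FOXA2. Sites that FOXA2 gained in CFPAC1 with HOXB8 were often Flag-HOXB8 sites. Of 1988 gained sites, 49.7% (47.6 to 51.9) overlapped a Flag-HOXB8 peak of the same cells, against 9.24% (8.52 to 10.0) of 5844 lost and 34.997% (34.4 to 35.6) of 28580 kept sites. Sites called by a single control library alone overlapped such a peak in 0.603% to 6.45% of cases. All 5 of the strongest gained sites did so. They lay in USP25 (chromosome 21, 15767936 to 15768531) and CAMKMT (chromosome 2, 44663571 to 44664104) and near ERCC4, a DNA repair nuclease gene (36.7 kb, chromosome 16, 13883124 to 13884312), SGO2 (1.01 kb, chromosome 2, 200524793 to 200525430) and IMPA1 (12.9 kb, chromosome 8, 81643684 to 81644260). Among the strongest lost sites, that near OTUD1 (18.3 kb, chromosome 10, 23460475 to 23460959) overlapped a Flag-HOXB8 peak, and those in TMEM245 and DNM3 and nearest to PACRGL and CYTL1 did not.

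Gained sites rarely overlapped AP-1 peaks of CFPAC1 cells without added HOXB8, with 5.99% at a JUNB and 9.61% at a FOS peak, against 57.6% and 62.4% of kept and 40.8% and 47.3% of lost sites. The classes themselves bear on these shares, since gained sites exclude all FOXA2 peaks of the control libraries. Those of the CFPAC1 WT library alone met 64.9% of JUNB and 51.3% of FOS peaks. AP-1 binding in the cells with HOXB8 was not analysed here. Gained sites were FOXA2 sites in PANC1 in 11.8% of cases (10.4 to 13.3), lost sites in 12.5% and kept sites in 32.3%. The classes bear on these shares too. Gained sites could meet only PANC1 sites called in no control CFPAC1 library, and lost and kept sites only those called in several. The shares thus do not show whether FOXA2 moved towards PANC1 sites with HOXB8. Flag-HOXB8 peaks of PANC1 overlapped 14.9% of gained, 5.03% of lost and 15.6% of kept sites. With the empty-vector library as the only control, 4779 sites were gained and 36.5% of them overlapped a Flag-HOXB8 peak. There was 1 HOXB8 library, and no test across libraries was made.

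**Figure D3:**
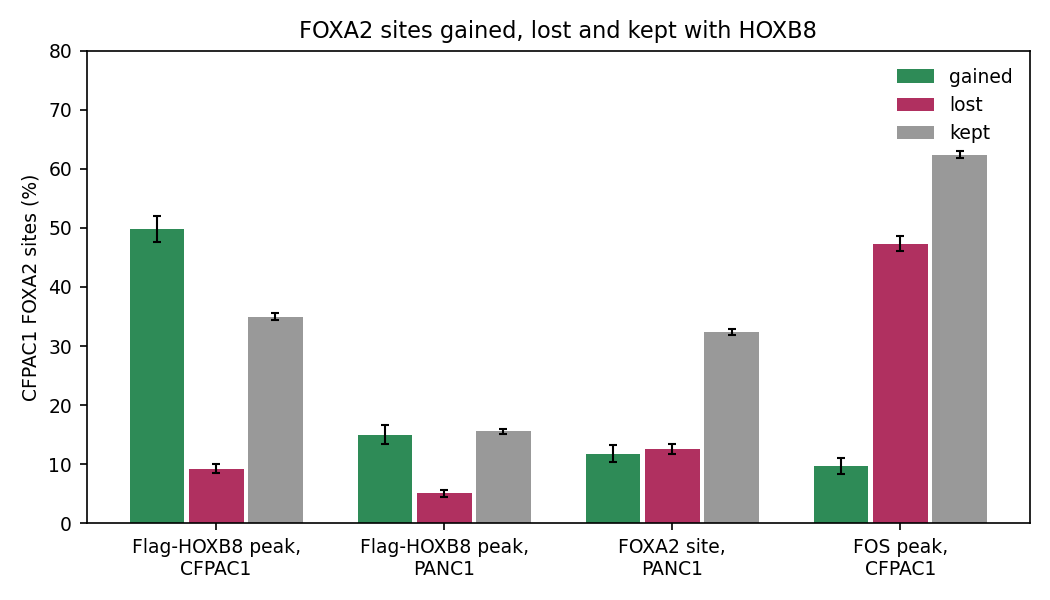
Share of CFPAC1 FOXA2 sites gained (1988), lost (5844) and kept (28580) with HOXB8 (vertical axis, percent) that overlapped each kind of peak or site, with bars starting at 0 and 95% Wilson intervals. The Flag-HOXB8 share in CFPAC1 was 49.7%, 9.24% and 34.997%.

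In each line, more Flag-HOXB8 peaks overlapped FOXA2 sites of that line than of the other. Of Flag-HOXB8 peaks, 45.1% (44.5 to 45.7) of the 24714 in CFPAC1 overlapped a CFPAC1 FOXA2 site and 18.0% a PANC1 FOXA2 site, while 46.1% (45.4 to 46.9) of the 16618 in PANC1 overlapped a PANC1 and 31.2% a CFPAC1 FOXA2 site. Seen from the sites, 28.8% of CFPAC1-only FOXA2 sites held a Flag-HOXB8 peak in CFPAC1 and 2.13% in PANC1. For PANC1-only sites the shares were 3.72% and 29.0%, and for shared sites 34.7% and 39.3%. A preference for sites of the same line was not particular to Flag-HOXB8. By summit, CFPAC1 JUNB peaks held 48.7% of CFPAC1-only and 1.12% of PANC1-only sites. No Flag library came from cells without Flag-HOXB8, so background of the Flag antibody could not be set apart. The PANC1 Flag library was of the early protocol and the CFPAC1 one of the late. Near the HOXB8 gene, 29 Flag-HOXB8 peaks were called in PANC1 and 3 in CFPAC1.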

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

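Of the tests below, the following were chosen only after the result was seen: the comparison of FOXA1 lists for edited-only sites, the shifted gene list, the H3K27ac cover of HOXB and HOXC, and the counts of splits for the site classes.

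A library stood apart from the other 5 CFPAC1 control libraries in 2 of 11 quantities examined, where chance gives about 1 in 20. The share of strongest peaks within 1 kb of a gene end was 4.02% in CFPAC1 FOXA2 replicate 1. The CFPAC1 WT library alone among the 6 called 23050 sites.

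The libraries labelled FOXA2KO held FOXA2 antibody peaks at 97.7% of control sites. Peaks let in by the loose calling limit are argued against, since 99.1% of control sites were still called in both at a −log10 q of at least 10. Libraries made from the control cells stay open. Sites of the edited clone alone lay in the FOXA1 list of that clone 30.2 percentage points more often than in that of the control clone (55.1% against 24.9%). Those sites exclude both control FOXA2 lists, whose common sites nearly all lay in the control FOXA1 list, so their choice favours this gap in advance. A clone mislabelled as a whole or edited incompletely would also pass this test. Without that choice of sites, Spearman correlations of fold between the FOXA2 lists labelled FOXA2KO and the control FOXA1 list were 0.851 and 0.857. With the FOXA1 list of the same clone they were 0.926 and 0.934, with 1 FOXA1 list per clone. An antibody that also brings down FOXA1 may be a source, since 87.1% of the 49670 sites lay in FOXA1 peaks of the same clone. The 99.2% in the control clone is of 26129 sites, limited by the short FOXA2WT replicate 2 list, so the values do not decide. Spearman correlations of fold between the FOXA1 and the 2 FOXA2 antibody lists were 0.926 and 0.934 in this clone, against 0.942 between the 2 FOXA2 lists. In control cells they were likewise 0.934 and 0.922, against 0.917, so these do not decide either. FOXA2 protein was not analysed here.

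Sites gained with HOXB8 lay at Flag-HOXB8 peaks. Weak peaks near the threshold, which predict a share under 10%, are argued against, since 74.6% of the 397 with a −log10 q of at least 10, among 2001 gained sites merged without the PANC1 lists, lay at such peaks. With that limit on all lists, Flag-HOXB8 and controls included, the share was 45.8% of 1012 gained sites, below the 49.7% of all gained sites but above 10%. Peaks that any libraries of the same cells share stay open: 15.0% of these 2001 sites lay at Flag-HOXB8 peaks of PANC1, above 5 control libraries (at most 3.08%), but the sixth called only 31 sites alone and its 6.45% has an interval of 1.79 to 20.7. No biological explanation was tested, with 1 HOXB8 library.

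HOXB and HOXC lay near many PANC1-only sites. Neighbouring genes counted several times stay open as a source. A permutation test of 14524 shifts of the list gave p = 0.00262, but the shifts keep the order of genes and not their spacing. HOX genes of a cluster lie close together and share sites, so the shifted lists may count shared sites less often. A lack of H3K27ac across HOXB in CFPAC1 is argued against, with 18.6% of it under peaks of both libraries (25.0% and 21.5% in each) against 2.30% of the genome (3.19% and 3.001%), while at HOXC a lack stays open, with 0.431% covered but 0 of 13 PANC1-only sites in such peaks against 5.87% elsewhere (1 of 17 at HOXB), too few to decide. This test and its rule were changed 4 times after values were seen: earlier forms took all HOX sites together (3.03%, 0.537 to 15.3), which would have counted for the explanation, the lowest of 4 clusters, which left it open, the cover alone, which would have counted against it at HOXB and for it at HOXC, and cover with sites, which left both open, and HOXA (11.96%) and HOXD (1.25%) are not in the present form. More copies of the regions in PANC1 could also add to it, since 32.1% (22.7 to 43.0) of classed sites in the flanks were PANC1-only, against 64.7% inside and 18.6% in the genome, and a difference between the lines in HOX gene activity was not tested.

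Other splits of the 9 libraries into 6 and 3 bear on the site classes. As many CFPAC1-only sites as the real 21491 came from 1 of 84 splits, the real one, with 7242 the highest of the others. That is the smallest share 84 splits can give, and this count was chosen after the result was seen. It sets the real split apart among these 9 libraries. It cannot tell the line from list length, since CFPAC1 lists were longer on average. For PANC1-only sites 2 of 84 splits gave as many as the real 7211. The other, which set apart the CFPAC1 WT, CFPAC1 Empty and FOXA2WT replicate 1 libraries, gave 15366, and these are the longest lists, so list length is a structure of these samples beside the line. For gene lists, 5 of 84 splits gave as many pairs of list and class past the threshold as the real 3, with 3 the highest of the others, so chance is not excluded for that number. As many HOX genes near sites of the 3 libraries alone (30) came from 2 of the 84.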

How the results depend on the processing

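The alternatives with a common q limit of 0.05, the shifted gene list, the distance that counts the inside of a gene, and the gene lists with a library left out were chosen after seeing the data. Of 532 alternative values, 436 kept their side of the threshold or stayed within their limits, 66 moved, 29 fell short of the threshold, 1 newly passed it and 0 reversed. For gene lists, a change of direction counted as reversed only where a value passed the threshold. Lists short of it throughout count as kept whatever their direction, and the shifted lists were not checked for direction. For control sites in edited clones the limits were wide, the SD between same-numbered pairs. These were 15.2 percentage points for FOXA2KO and 26.1 for FOXA1KO. Of those that kept, 28 concern named sites whose choice fixed the outcome and show no stability. Where no cause is given, the cause was not tested. The motif counts were not run, since no genome sequence was used here. Depth per sample is unknown, so what it limits could not be measured.

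Counts of sites followed how many peaks and libraries were required. At a −log10 q of at least 10 there were 12779 CFPAC1-only, 4440 PANC1-only and 5301 shared sites. With the 10000 strongest peaks per library, CFPAC1-only, PANC1-only and shared sites numbered 5511, 5355 and 2938, so the excess of CFPAC1-only over PANC1-only sites was nearly gone at equal list length. Calls in all libraries of a line gave 10571, 3329 and 5028, and shared sites numbered 4076 when peaks had to cover at least 50% of a site. PANC1-only sites numbered 4165 in the early and 15074 in the late protocol. With a library left out, CFPAC1-only sites ranged from 21768 to 29818, PANC1-only from 3626 to 8062 and shared from 6832 to 11215.

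Replicate numbers do not pair these samples, since equal numbers name different kinds of cells in the 2 lines. With the replicate number as a block there were 14737 CFPAC1-only, 5532 PANC1-only and 5668 shared sites. The same-numbered pairs gave 87.6% of control and 61.5% of edited sites for FOXA2KO, and 75.6% and 71.8% for FOXA1KO. With 2 pairs, no correlation of numbers was judged.

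The CFPAC1 minus PANC1 differences of shares kept their signs. In the early protocol they were 35.2 (JUNB), 31.4 (FOS), 2.61 (H3K27ac) and −2.87 (gene end) percentage points, and with 1 antibody lot 36.6, 33.0, 3.65 and −2.05, without passing the threshold. JUNB and FOS in both cases, and gene ends in the early protocol, had the smallest p that the fewer splits allow. For the others the cause was not tested. H3K27ac differed by 0.433 among the 2000 strongest peaks, and gene ends by −1.83 among all peaks. With a library left out the differences ranged from 37.0 to 38.8, 33.6 to 35.3, 2.58 to 4.84 and −3.03 to −1.56. All 4 fell short without PANC1 FOXA2 replicate 1, where 28 splits remain (adjusted exact permutation p = 0.0714), H3K27ac also without the PANC1 empty-vector library (0.107) and gene ends without PANC1 FOXA2 replicate 2 (0.0714).

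In edited clones, leaving out 1 library gave 71.8% to 98.6% of control and 43.7% to 87.2% of edited sites for FOXA2KO, and 53.6% to 94.4% and 54.0% to 93.3% for FOXA1KO, with the extremes set by FOXA2WT replicate 2. With 10000 peaks per library 83.5% of FOXA2KO sites were in both controls. For the FOXA1 antibody in FOXA1KO, control peaks were found in 81.9% (10000 peaks), 47.7% (summits within 100 bp) and 49.3% (at least 50% covered) of cases. The converse was 82.4%, 78.8% and 91.9%, and 96.4% at the stricter q. In FOXA2KO these were 85.0%, 69.0% and 77.1%, with 83.2% at the stricter q, and conversely 85.1%, 69.1%, 77.4% and 84.5%.

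With HOXB8, the stricter q, 10000 peaks per library and the empty vector as the only control gave 1012, 896 and 4779 gained and 3178, 1268 and 17493 lost sites. Flag-HOXB8 shares in that order were 45.8%, 45.2% and 36.5% of gained, 6.17%, 14.4% and 7.75% of lost, and 26.6%, 33.8% and 33.7% of kept sites, and by summit 47.3%, 7.05% and 30.8%. Gained sites were PANC1 FOXA2 sites in 18.0% (10000 peaks) and 14.6% (empty vector). PANC1 Flag-HOXB8 peaks met PANC1 sites in 52.5%, 41.9% and 44.6% (stricter q, 10000 peaks, summit) and CFPAC1 sites in 32.5%, 18.5% and 30.3%. CFPAC1 Flag-HOXB8 peaks met CFPAC1 sites in 41.8%, 28.5% and 44.3%, and PANC1 sites in 16.4% and 14.7%.

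Among gene lists, the basal-like call was lost at 20 kb (63.6%), at 100 kb (100%), by the nearest gene (88.9%), with 10000 peaks (72.7%), inside the gene or within 50 kb (100%), with the shifted list (100%) and without CFPAC1 FOXA2 replicate 1 or 2, FOXA2WT replicate 2 or any PANC1 library (100% to 100%). Its adjusted p over these libraries ran from 0.0864 to 0.284. The HOX deficit was lost with 10000 peaks (41.9%), and epithelial genes passed at 100 kb (97.5%, adjusted p = 0.0132, Fisher's exact test). With 10000 peaks 1 pair of list and class passed.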

Other observations

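The comparisons below were chosen after the data were seen. Some of the strongest differing sites of a clone recurred with the other antibody. Sites called in the clone labelled FOXA2KO alone included ALDH1A2, SEMA6D and CDH8 with the FOXA2 and the FOXA1 antibody, and sites of its controls alone included PARD3B, SLC8A1 and MDGA2 with both. In the clone labelled FOXA1KO, DPP10 and POFUT3 were missing and SPANXN2 and FLRT2 present with both. Some of these were missing from both edited clones. The DPP10 site was also absent from the FOXA1 list of the FOXA2KO clone, and the PARD3B site from the FOXA2 lists of the FOXA1KO clone. Of the 1129 FOXA2 antibody sites missing from the FOXA1KO libraries, 94.7% lay in the FOXA1 list of the control clone and 13.4% in that of the FOXA1KO clone, and 73.6% were called in both libraries labelled FOXA2KO. For the 23620 sites common to controls and FOXA1KO libraries, these shares were all higher, at 99.6%, 92.7% and 99.4%. The class is defined by absence from the FOXA1KO libraries, and the FOXA1 list of that clone was the shorter, with 31610 peaks against 52239. Both favour the gap between the FOXA1 lists in advance. The 2287 FOXA2 antibody sites of the FOXA1KO libraries alone lay about equally often in both FOXA1 lists, with 22.5% (20.8 to 24.2) in that of the control clone and 22.2% (20.6 to 24.0) in that of the FOXA1KO clone. Of the 6274 sites of the FOXA2KO libraries alone, 44.9% overlapped H3K27ac peaks of unedited CFPAC1 cells, against 58.2% of the 25525 sites common to both and 7.69% of the 221 of the controls alone, and 12.4% were called in none of the 4 other control libraries. These H3K27ac shares count any overlap of at least 1 bp and cannot be set against the shares by summit above. No test was made.

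Line-specific sites were spread unevenly over chromosomes. Chromosome 4 held 8.70% of CFPAC1-only and 4.56% of PANC1-only sites, and chromosome 14 held 4.29% and 2.00%. Chromosome 19 held 1.02% and 2.63%, and chromosome 6 held 5.91% and 8.46%. The number of copies of each chromosome in the lines was not analysed here.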
